A study of Sus scrofa with 12 samples.

How the data were processed

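Uterine RNA of 12 newborn gilts was sequenced, with 4 animals in each of 3 groups: PND0 (within 1 h of birth), PND2N (nursed for 48 h) and PND2R (fed milk replacer for 48 h), the day 2 uteri being taken at 50 h. The labels describe RNA isolated with a column kit and a library kit for messenger RNA. According to the processing notes of the authors, reads were converted with bcl2fastq and the build was Sscrofa10.2. The aligner, the counting and the normalization are not given in the sources used here. Each library was matched to its group by the library number in its label. The labels give no litter, date or batch, and the replicate numbers pair no animals, so no covariate or block was fitted.

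The deposited table gave 1 value per gene and library as signal, a normalized linear value made by the authors, with 1 as its lowest value. Column totals were between 26534074 and 29544130. Low values clustered on multiples of 1 step per library, but only 35.3% to 53.7% of them were whole multiples (within 0.02 steps), so read counts were not recovered and no count test was used. Divided by that step, the totals equal 22693932 to 35517165 reads (median 26694220), which gives the depth only roughly. No binomial interval was computed for lack of counts. The 10 highest genes took 3.43% to 5.38% of a library's total, no pair of libraries was identical, and the lowest correlation between libraries was 0.935.

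All 20390 genes of the table are protein-coding. Their positions are those of the table. Names came from the table and, for 6403 of the 13716 genes listed there under LOC placeholders, from an NCBI gene table of a later assembly (Sscrofa11.1), used for names only, which held 14468 of the 20390 entries. In addition, 11 symbols that a spreadsheet had turned into dates were restored. This gave a symbol for 13077 genes. For 4 symbols the table's entry stands for another gene, and these are not named. Of 1007 entries in 40 gene lists (26 of pathways and 14 of cell type markers), 802 were matched.

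Values were taken as log2(value + 1). A gene was tested if it exceeded 1 in at least 4 of the 12 libraries, which left 16862. All 12 libraries entered 1 fit in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with trended, robust empirical Bayes moderation. The contrasts were PND2N versus PND0, PND2R versus PND0 and PND2N versus PND2R, all two-sided, with an F test for any difference among the groups. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no fold threshold. Gene lists with at least 5 measured members were tested with camera from limma, with a preset correlation between genes of 0.01 and adjustment over the lists of a contrast. Camera compares a list with all other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

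Agreement of the comparisons with birth was measured by Pearson and Spearman correlation of the log2 changes across genes. Since both use the same PND0 libraries, it was set against 100 simulations of unchanged groups and against fits in which the PND0 libraries were divided 2 and 2. The structure of the samples was read from principal components of the tested log2 values.

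The tests, the gene lists, the naming of genes and the alternatives were fixed before the data were examined, except where an alternative or a gene is said to have been chosen later. The genes named are the 10 with the largest rise and the 10 with the largest fall in a contrast, among those with a symbol, past the threshold, without overlap of the 4 and 4 libraries and with a mean of at least 10 in the higher group. Those of unknown function were left out, which kept 14 of 20 for PND2N versus PND0 and 17 of 20 for PND2R versus PND0. Further named genes are up to 4 members with the smallest unadjusted p of each list described, and a panel of 19 uterine genes, 17 of them measured.

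The alternatives were added values of 0.1 and 5, no filter and a filter at 10, TMM scaling (written from its definition, with trims of 0.3 and 0.05) and quantile normalization, only the groups compared in the fit, plain empirical Bayes, library quality weights, a 2-fold threshold, an estimated correlation for camera, and each library left out in turn. Chosen after seeing the data were fits without 3 libraries that stood apart, leaving 9, of which 2 were replacer-fed. Also chosen then were fits with the score of each library on the first within-group axis as a covariate. The axis was found with group means taken out, but the scores keep the group differences. They ran from 47.5 to 59.6 in PND0, -125.4 to 61.2 in PND2N and -109.4 to 36.9 in PND2R. The covariate therefore overlaps with age and can take up part of a change from birth. After seeing the data the structure was also read again under the other added values, filters and scalings. To ask what chance gives, the 35 splits of 8 libraries into 4 and 4 were refitted for each contrast, and 100 drawn splits of the 12 libraries for the F test. The median loading of each cell type list on an axis was set against 10000 random lists matched on expression.

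The procedure was tested on simulated data with 200 changed genes in 3 simulations per comparison. With noise that kept the shared axes of the real libraries, 26.4% to 32.8% of genes changed by 1 on the log2 scale were recovered. Of those changed by 2, 70.6% to 74.1% were recovered, and of those changed by 3, 88.4% to 92.4%, with 0 false calls. This 0 comes from 3 simulations per comparison and does not bound the false calls in the real libraries. Among real splits that mixed nursed and replacer-fed libraries, 2 called 6202 and 2674 genes and the others called 0. With noise independent between genes there were up to 10 false calls. With such independent noise, camera found a cell cycle list moved by 0.5 in 20 of 20 simulations with 0 other lists called. In the real libraries the estimated correlation was 0.504 in the cell cycle list and 0.902 in the ribosomal list. These simulations therefore do not measure false list calls where the genes of a list move together. The TMM factors came within 0.0773% of the known ones.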

Results

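Uterine RNA of newborn gilts (young female pigs) was profiled by sequencing in 3 groups of 4 animals, 1 library per animal. Uteri of the PND0 group were taken within 1 h of birth. The PND2N gilts nursed freely for 48 h and the PND2R gilts drank commercial milk replacer for 48 h, and uteri of both were taken 50 h after birth. The animals were crossbred, from Landrace, Yorkshire, Duroc and Hampshire stock. The deposited table held normalized values of 20390 protein-coding genes, with 1 as its lowest value in every library. Library totals of these values ran from 26534074 to 29544130, and the spacing of the low values corresponded to 22693932 to 35517165 reads per library. Between 17.8% and 22.1% of genes sat at the value of 1, so a gene at that level was not detectable at this depth rather than shown to be absent. Group levels are given as normalized value, mean ± SD of 4 animals, and changes as log2 change ± SE.

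Some day 2 libraries stood apart from the others, with high DES among other differences, and some newborn libraries differed in epithelial genes. DES, the intermediate filament protein of muscle cells, stood at 40049, 33144 and 29022 in PND2N 1, PND2R 2 and PND2R 3, against 7460.1 to 23440 in the other 9 libraries. ACTG2, an actin of smooth muscle, stood at 9052, 5536 and 5086 in these libraries and between 1919 and 5860 in the others. VWF, the von Willebrand factor of endothelium, was 24.2, 55.8 and 90.2 there and 591 to 3194 in the others. The median of the endothelium list, relative to each gene's mean over the 12 libraries, was 0.09, -0.07 and -0.14 in the same 3 libraries, within the -0.38 to 0.59 of the others, so VWF does not stand for its list. These libraries lay at one end of the first principal component, which held 58.5% of the variance of the log2 values, and 46.5% of the spread along it lay between groups. Within the newborn group, KRT8, a keratin of simple epithelia, was 49821 and 51645 in PND0 1 and PND0 2 but 14444 and 11100 in PND0 3 and PND0 4. KRT18 and KRT19, other keratins of simple epithelia, followed the same split, with 7511, 7886, 1902 and 1753 for KRT18 and 20727, 23595, 7196 and 4787 for KRT19. The median of the epithelium list was 0.74, 0.71, -1.14 and -1.30 in PND0 1 to PND0 4. This split ran along the second component, with 12.9% of the variance. The single genes and libraries of this paragraph were chosen after their values were seen. The labels name no litter, date or batch to set beside these differences.

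**Figure D1:**
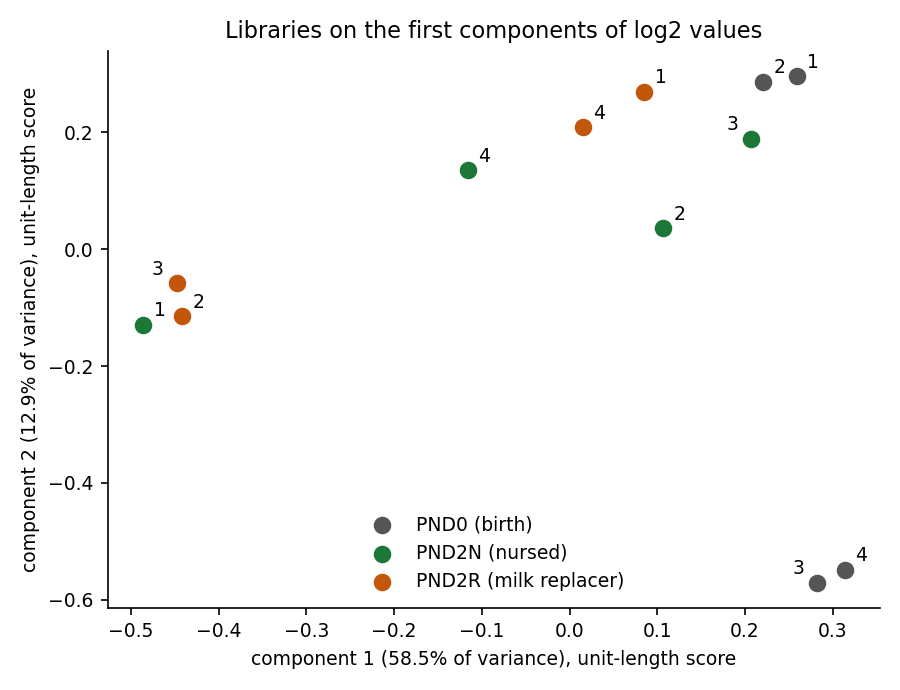
Scores of the 12 libraries on the first and second principal components of the log2 values (unit-length scores, no units), 1 point per library, colored by group and numbered by replicate. PND2N 1, PND2R 2 and PND2R 3 lie together at the low end of the component with 58.5% of the variance, and PND0 3 and PND0 4 lie apart from PND0 1 and PND0 2 on the component with 12.9%.

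The comparison of PND2N with PND0 asked what the first 2 days of life with nursing change in the uterus. MMP7 (matrilysin, an epithelial matrix protease; chromosome 9, 38104906 to 38115301 on Sscrofa10.2) rose from 28.8 ± 20.5 at birth to 562 ± 208 in nursed gilts, a log2 change of 4.48 ± 0.49 (adjusted p = 0.00427, n = 4 per group). The monocyte-attracting chemokine CCL8 rose from 18.5 ± 14.5 to 109 ± 30.3, the angiotensin precursor AGT from 48.0 ± 36.2 to 269.8 ± 101, and GRIN2C, a subunit of NMDA glutamate receptors, from 6.83 ± 6.20 to 47.9 ± 23.4. BBOX1, which carries out the last step of carnitine synthesis, rose by 2.38 ± 0.45, and SKA1, a kinetochore protein of dividing cells, by 1.98 ± 0.29. IL17F, a cytokine gene, rose from 298 ± 100.5 to 1416 ± 806, and its interval (chromosome 7, 52019584 to 52045758) ended just before MCM3, a subunit of the replication helicase, which starts at 52045996 and held 3024 and 4419.9. Among the falls, ZBTB16, a transcription factor that glucocorticoids and progestins induce, dropped from 787 ± 291 to 62.1 ± 44.5, a log2 change of -4.36 ± 1.07. HIPK2, a nuclear protein kinase, fell from 356 ± 109 to 65.9 ± 31.8, the semaphorin receptor PLXNA4 from 62.1 ± 14.7 to 10.17 ± 8.72, and HIF3A, of the family of hypoxia-inducible factors, from 49.6 ± 19.3 to 8.61 ± 6.14. PPP1R3G, a glycogen-targeting subunit of a phosphatase, fell from 37.2 ± 10.9 to 1.04 ± 0.0884, the LIM homeobox gene LHX4 from 23.5 ± 13.3 to 1.21 ± 0.318, and GREB1, an estrogen-induced gene, from 34.7 ± 28.8 to 2.09 ± 1.29. The last 3 of these ended near the lowest value of the table, so the size of their fold depends on the value added before the logarithm. Single libraries weigh on some of these means: without PND0 4 the newborn means of GRIN2C and GREB1 were 3.97 and 20.4, without PND0 2 that of CCL8 was 11.6, and the nursed means of PLXNA4 and HIF3A were 6.23 without PND2N 3 and 5.62 without PND2N 4. Without the 3 libraries of high DES the GRIN2C and AGT calls ended (adjusted p = 0.0563 and adjusted p = 0.0587), as they did with the axis score as a covariate (adjusted p = 0.0592 and adjusted p = 0.0613), where the change of ZBTB16 was -2.74. That score was higher in the newborn libraries than in all day 2 libraries but PND2N 3. As a covariate it can therefore take up part of a change from birth. These are the 14 genes of known function among the 20 with the largest rises and falls. By the rule that chose them, the 4 libraries of one group lay above the 4 of the other in each. Their adjusted p, under the threshold by the same rule, ran from 0.00427 to 0.0492.

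With the preset correlation between genes, lists of cell division and mitochondrial energy metabolism genes were higher in nursed gilts than at birth. None of these list calls held with an estimated correlation. Of 27 measured cell cycle genes, 23 had a positive change, 3 rose over all genes tested and 12 rose when adjusted over the list alone. The list's median log2 change was 0.71 (list adjusted p = 2.29e-06; adjusted p = 0.507 with an estimated correlation). The mitotic kinases AURKA and AURKB rose by 1.10 ± 0.18 and 0.77 ± 0.18, cyclin B2 (CCNB2) rose by 1.19 ± 0.24, and FOXM1, a transcription factor of cell division, was 459 ± 85.7 and 827 ± 159 without passing (adjusted p = 0.0501). Of 33 oxidative phosphorylation genes, 29 had a positive change, 3 rose over all genes tested and 14 rose adjusted over the list alone, with a median of 0.47 (list adjusted p = 4.26e-07; adjusted p = 0.507 with an estimated correlation). Subunits of complex I (NDUFS4, 1.43 ± 0.28, and NDUFV2, spelled NUDFV2 in the table, 0.80 ± 0.19) and of ATP synthase (ATP5O, 0.96 ± 0.19) rose, while NDUFB5, another complex I subunit, was 1745 ± 356 and 2576 ± 199.9 and did not pass. In the fatty acid oxidation list 21 of 26 members had a positive change, 4 rose over all genes tested and 7 adjusted over the list alone, with a median of 0.34 (list adjusted p = 8.86e-04; adjusted p = 0.129 with an estimated correlation). They were CPT1A, which controls the entry of fatty acids into mitochondria and went from 3705 ± 657 to 8157 ± 1327, the carnitine carrier SLC25A20 (1.07 ± 0.16), the thiolase ACAA2 (0.59 ± 0.12) and the mitochondrial carrier UCP2 (1.08 ± 0.24). For cytosolic ribosomal proteins the median of 44 genes was 0.22 (list adjusted p = 0.0175; adjusted p = 0.791 with an estimated correlation). None of them passed over all genes in limma, nor adjusted over the list alone, and 3 had an unadjusted p under 0.05. The lowest unadjusted p values belonged to RPS25, RPL32, RPSA and RPS24, with log2 changes of 0.77 ± 0.24, 0.55 ± 0.22, 0.57 ± 0.26 and 0.55 ± 0.25. The ribosomal call was absent without the 3 libraries of high DES (adjusted p = 0.422) and under quantile normalization (adjusted p = 0.111), and with the axis score as a covariate the median turned to -0.052 (adjusted p = 0.615). Over all genes tested 3 cell cycle, 1 oxidative phosphorylation and 2 fatty acid oxidation genes rose without these 3 libraries, and the calls on AURKB, ACAA2, UCP2, ATP5O and NUDFV2 ended (adjusted p from 0.0565 to 0.0863). Their changes there were 0.67, 0.58, 1.02, 0.86 and 0.67.

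Lists of immune genes were higher as well. The list of cytokines, chemokines and acute phase proteins had 27 of 30 members with a positive change and a median of 0.60 (list adjusted p = 4.21e-04; adjusted p = 0.0480 with an estimated correlation). This was the only one of the 12 called lists to hold with an estimated correlation. With that correlation it did not hold without the 3 libraries of high DES (list adjusted p = 0.199). Of its members 3 rose over all genes tested and 4 adjusted over the list alone: besides CCL8, the monocyte chemokine CCL2 rose by 1.93 ± 0.38 and CXCL14 by 1.29 ± 0.31, and CXCL12, a chemokine of stromal cells, was 3118 ± 613 and 5132 ± 1342 without passing. For the interferon response, 22 of 25 members had a positive change with a median of 0.65 (list adjusted p = 3.80e-04; adjusted p = 0.507 with an estimated correlation). None of them passed over all genes in limma, 3 rose adjusted over the list alone and 11 had an unadjusted p under 0.05. The interferon-induced genes HERC5, BST2, GBP2 and IFI44 had changes of 1.44 ± 0.40, 1.62 ± 0.47, 0.86 ± 0.26 and 0.87 ± 0.28. Among 20 complement genes 14 had a positive change, 4 rose over all genes tested and 5 adjusted over the list alone, with a median of 0.35 (list adjusted p = 0.0459; adjusted p = 0.507 with an estimated correlation). The C1q chains C1QB and C1QC, which start the classical pathway, rose by 0.95 ± 0.22 and 1.13 ± 0.26, and the inhibitors SERPING1 and CD59 rose by 0.99 ± 0.23 and 0.60 ± 0.14. The macrophage list shares C1QB and C1QC with it. There, 11 of 15 members had a positive change, 3 rose over all genes tested and 5 adjusted over the list alone, with a median of 0.48 (list adjusted p = 0.0184; adjusted p = 0.507 with an estimated correlation). Its other named members were LAPTM5, a lysosomal protein of leukocytes (0.75 ± 0.19), which rose, and AIF1, an actin-binding protein of macrophages, at 247 ± 110.5 and 543 ± 109 without passing. In the antigen presentation list 15 of 19 members had a positive change with a median of 0.49 (list adjusted p = 0.0348; adjusted p = 0.551 with an estimated correlation). None of them passed over all genes in limma, 6 rose adjusted over the list alone and 8 had an unadjusted p under 0.05. The swine MHC genes SLA-DQA1, SLA-DMA, SLA-8 and SLA-DMB had changes of 1.35 ± 0.36, 0.96 ± 0.26, 0.89 ± 0.25 and 0.74 ± 0.23. The calls on C1QB, C1QC, CD59, CXCL14 and LAPTM5 ended without the 3 libraries of high DES (adjusted p from 0.0535 to 0.0852). There the changes of C1QB, C1QC, CD59 and CXCL14 were 0.94, 1.16, 0.61 and 0.98. The LAPTM5 call also ended with the axis score (adjusted p = 0.0529), where the change of SERPING1 was 0.65.

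Immediate early, IGF system and hypoxia lists were lower in nursed gilts than at birth. Of 20 immediate early genes 4 had a positive change and the median was -0.58 (list adjusted p = 0.00106; adjusted p = 0.297 with an estimated correlation). None of them passed over all genes in limma, 6 fell adjusted over the list alone and 10 had an unadjusted p under 0.05. The transcription factors KLF6, JUN (C-JUN in the table) and FOS and the matricellular gene CTGF (CCN2 in the table) had changes of -1.02 ± 0.29, -1.15 ± 0.32, -1.14 ± 0.35 and -1.04 ± 0.32. In the IGF system 5 of 19 members had a positive change, 3 fell over all genes tested and 5 adjusted over the list alone, with a median of -0.27 (list adjusted p = 0.0260; adjusted p = 0.297 with an estimated correlation). The IGF1 receptor gene IGF1R went from 2967 ± 541 to 1421 ± 159, IGF2R, whose product clears IGF2, from 8166 ± 858 to 4443 ± 760.3, and the adaptor IRS1 from 3796 ± 926 to 1558 ± 406. The insulin receptor INSR was 869 ± 180.2 and 226 ± 125 without passing (adjusted p = 0.0673). Among 25 hypoxia response genes 4 had a positive change, 2 fell over all genes tested and 5 adjusted over the list alone, with a median of -0.24 (list adjusted p = 9.67e-04; adjusted p = 0.129 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase, fell by 1.10 ± 0.21 and the angiogenic factor VEGFA fell by 0.70 ± 0.16. The collagen hydroxylase P4HA1 and ANKRD37, both hypoxia-induced, had changes of -0.83 ± 0.21 and -1.16 ± 0.34 and did not pass. The hypoxia median was -0.44 without the 3 libraries of high DES and -0.40 with the axis score.

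In all, 322 genes rose and 238 fell of 16862 tested with limma, 4032 had an unadjusted p under 0.05, and 327 of those past the threshold changed at least 2-fold. The libraries of the groups did not overlap for 16.02% of genes, where chance gives 2.86%. The count rests on single libraries: in place of 560 genes, 200 passed without PND0 1, 231 without PND0 3, 41 without PND0 4, 91 without PND2N 1, 127 without PND2N 2, 26 without PND2N 4, 341 without PND2R 2 and 202 without PND2R 4. Without PND2N 1, PND2R 2 and PND2R 3 together 275 genes passed, with the axis that parts them as a covariate 1213, and with only the groups compared in the fit 7. Of the 37 calls on genes named for this comparison, CPT1A, LHX4, MMP7 and PPP1R3G held whichever library was left out, 24 held without the 3 libraries together and 34 with their axis as a covariate. Without PND0 1, 2, 3 or 4 the number of these calls lost was 25, 11, 20 or 30. It was 28, 24, 7 or 33 without PND2N 1, 2, 3 or 4, and 7, 9, 15 or 19 without PND2R 1, 2, 3 or 4. The VEGFA call also ended under TMM scaling (adjusted p = 0.0504). The lists of oxidative phosphorylation, cell cycle, interferon response, cytokines, fatty acid oxidation, hypoxia response and immediate early genes were called in all 12 such fits. Without PND0 4 the adjusted p became 0.0624 for macrophages, 0.224 for antigen presentation, 0.122 for complement, 0.401 for ribosomal proteins and 0.0820 for the IGF system. The medians of these lists were then 0.32, 0.23, 0.17, 0.10 and -0.11. Without PND0 3 it became 0.0933 for complement, 0.206 for ribosomal proteins and 0.0513 for the IGF system. Leaving out PND2N 3 gave 0.0539 for macrophages, 0.102 for antigen presentation, 0.105 for complement and 0.105 for the IGF system. Leaving out PND2N 2 gave 0.0664 for macrophages and 0.0869 for complement, and leaving out PND2N 1 gave 0.536 for ribosomal proteins. Leaving out PND2N 4 gave 0.0536 for antigen presentation, 0.0798 for complement and 0.147 for ribosomal proteins. With the axis score as a covariate the antigen presentation and complement calls ended as well (medians of 0.21 and 0.24; adjusted p = 0.189 and adjusted p = 0.122).

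The comparison of PND2R with PND0 asked the same of gilts fed milk replacer. CXCL13, a chemokine that attracts B cells, rose from 3.59 ± 1.78 at birth to 189 ± 239.9, a log2 change of 4.75 ± 0.86 (adjusted p = 0.00961, n = 4 per group). The acute phase gene SAA3 rose from 2.92 ± 1.92 to 76.5 ± 61.8, MMP7 from 28.8 ± 20.5 to 185 ± 45.8, CCL8 by 2.58 ± 0.49 and SKA1 from 73.9 ± 22.9 to 414 ± 85.6. The zinc transporter SLC39A12 rose from 2.95 ± 3.60 to 56.4 ± 48.8. SYCP3, of the synaptonemal complex of meiosis, rose from 2.02 ± 1.27 to 36.4 ± 18.4, and SPAG6, of the axoneme of motile cilia, from 3.12 ± 2.34 to 29.8 ± 11.4. ZBTB16 fell from 787 ± 291 to 23.4 ± 24.7 (-5.70 ± 1.07; adjusted p = 0.0113). LPL, the lipoprotein lipase that releases fatty acids from blood lipids, fell from 437 ± 124 to 47.2 ± 31.8, the ceramide synthase gene LASS2 (now CERS2) from 70.7 ± 11.9 to 6.51 ± 4.37, and PLA2G4E, of the phospholipase A2 family, from 179 ± 142 to 3.05 ± 0.887. SEMA3E, a secreted guidance molecule, fell by 3.93 ± 0.88, ADAMTSL3, a matrix glycoprotein, fell by 3.69 ± 0.71, the kainate receptor gene GRIK3 fell by 3.66 ± 0.90 and the potassium-chloride cotransporter SLC12A4 fell by 3.56 ± 0.90. GREB1 went from 34.7 ± 28.8 to 1.30 ± 0.608, near the lowest value of the table. PND2R 2 carried much of the CXCL13 level, with 548 against 41.8 to 84.9 in the other libraries of the group, and without it the mean was 69.5. The replacer-fed means of SLC39A12 and ZBTB16 were 35.7 and 12.8 without PND2R 1 and that of SAA3 was 46.8 without PND2R 4. The newborn means of SLC39A12 and SPAG6 were 1.16 and 2.04 without PND0 3, and that of GREB1 was 20.4 without PND0 4. Without the 3 libraries of high DES the changes were -4.15 for ZBTB16, -4.60 for PLA2G4E, -2.41 for SEMA3E, -2.34 for GRIK3 and -1.95 for SLC12A4. There the calls on PLA2G4E, SEMA3E, GRIK3, SLC12A4, SLC39A12, SYCP3 and CCL8 ended (adjusted p from 0.0501 to 0.0808). With the axis score the changes of ZBTB16, SEMA3E, GRIK3, SLC12A4, LASS2 and LPL were -3.42, -2.12, -1.83, -1.54, -2.25 and -2.27, and the GRIK3 and SLC39A12 calls ended (adjusted p = 0.0642 and adjusted p = 0.0882). These are 17 of the 20 genes with the largest rises and falls, those of known function. By the rule that chose them, the libraries of the 2 groups did not overlap in each. Their adjusted p, under the threshold by the same rule, ran from 0.00391 to 0.0286.

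Lists of cell cycle, respiratory chain, ribosomal, interferon and cytokine genes were higher in replacer-fed gilts than at birth. Of 27 cell cycle genes 20 had a positive change, 9 rose over all genes tested and 13 adjusted over the list alone, with a median of 0.61 (list adjusted p = 4.80e-04; adjusted p = 0.523 with an estimated correlation). AURKA rose by 1.30 ± 0.18, CCNB2 by 1.46 ± 0.24, AURKB by 1.04 ± 0.18 and FOXM1 by 1.04 ± 0.21. Of 33 oxidative phosphorylation genes 28 had a positive change, 14 rose over all genes tested and 20 adjusted over the list alone, with a median of 0.60 (list adjusted p = 6.53e-07; adjusted p = 0.501 with an estimated correlation). NDUFS4 went from 442 ± 52.7 to 1530.3 ± 359, NUDFV2 from 2008 ± 399 to 3975 ± 674, and the ATP synthase genes ATP5O and ATP5H rose by 0.99 ± 0.19 and 1.04 ± 0.24. For 44 ribosomal protein genes the median was 0.30 (list adjusted p = 9.93e-04; adjusted p = 0.646 with an estimated correlation). None of them passed over all genes in limma, nor adjusted over the list alone, and 10 had an unadjusted p under 0.05. RPL32, RPS25, RPL26 and RPS24 had changes of 0.69 ± 0.22, 0.75 ± 0.24, 0.71 ± 0.23 and 0.74 ± 0.25. The ribosomal call was absent without the 3 libraries of high DES (adjusted p = 0.0678, median 0.14), and with the axis score the median turned to -0.011 (adjusted p = 0.769). Of 25 interferon response genes 22 had a positive change, 6 rose over all genes tested and 9 adjusted over the list alone, with a median of 0.61 (list adjusted p = 7.40e-04; adjusted p = 0.501 with an estimated correlation). BST2, which holds budding viruses at the cell surface, rose by 2.23 ± 0.47, HERC5, a ligase for the ISG15 tag, by 1.53 ± 0.40, the RNA sensor gene DHX58 by 1.05 ± 0.29 and GBP2, a guanylate-binding protein, by 1.01 ± 0.26. Of 30 cytokine, chemokine and acute phase genes 25 had a positive change and 7 rose, both over all genes tested and adjusted over the list alone, with a median of 0.61 (list adjusted p = 7.40e-04; adjusted p = 0.0594 with an estimated correlation). Besides SAA3 and CCL8, CCL2 rose by 2.07 ± 0.38, and SAA2, another acute phase serum amyloid, went from 3.12 ± 1.75 to 15.4 ± 4.85. The genes that rose over all genes tested without the 3 libraries of high DES numbered 4 for the cell cycle, 1 for oxidative phosphorylation (median 0.43), 0 in limma for the interferon response and 1 for cytokines, while these lists still passed. The calls on AURKB, FOXM1, NUDFV2, ATP5O, ATP5H, BST2, HERC5, DHX58, GBP2, CCL2, CCL8 and SAA2 ended there (adjusted p from 0.0501 to 0.177). The change of GBP2 was 0.65 there, and that of CCL8 was 2.95 against 2.58 with all libraries. With the axis score the oxidative phosphorylation median was 0.31, ATP5H and GBP2 changed by 0.59 and 0.58, and the calls on ATP5H, BST2, HERC5, DHX58 and GBP2 ended (adjusted p from 0.0504 to 0.101). The highest NDUFS4 values were those of PND2R 3, PND2N 1 and PND2R 2, at 1929, 1859 and 1714.

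Immediate early, endothelial, glucocorticoid-responsive, IGF and hypoxia lists were lower in replacer-fed gilts than at birth. Of 20 immediate early genes 4 had a positive change, 5 fell over all genes tested and 8 adjusted over the list alone, with a median of -0.76 (list adjusted p = 0.00733; adjusted p = 0.412 with an estimated correlation). EGR1 went from 62.9 ± 17.3 to 10.997 ± 7.94 (7.16 without PND2R 2), EGR2 from 14.6 ± 5.18 to 2.99 ± 1.42, KLF6 from 6691 ± 2236 to 2697 ± 826 and JUN from 14442 ± 4496 to 6377 ± 567 (C-JUN in the table). Of 17 endothelium markers 4 had a positive change, 4 fell over all genes tested and 5 adjusted over the list alone, with a median of -0.58 (list adjusted p = 0.0255; adjusted p = 0.501 with an estimated correlation). The endothelial receptors TIE1 (TIE-1 in the table), FLT4, FLT1 and PECAM1 fell by 1.82 ± 0.25, 0.89 ± 0.18, 1.67 ± 0.42 and 0.77 ± 0.23. Of 20 glucocorticoid-responsive genes 6 had a positive change, 5 fell over all genes tested and 6 adjusted over the list alone, with a median of -0.51 (list adjusted p = 0.0385; adjusted p = 0.412 with an estimated correlation). Besides ZBTB16, the clock genes PER1 and CRY2 went from 368 ± 85.3 to 65.0 ± 8.95 and from 1731 ± 241 to 936 ± 122. The transcription factor KLF9 fell from 8.21 ± 3.41 to the lowest value of the table in all 4 libraries. In nursed gilts KLF9 was low as well, with a mean of 1.73. The glucocorticoid-responsive list had a median of -0.22 there without passing (list adjusted p = 0.101, and 0.0379 without the 3 libraries of high DES). In the IGF system of replacer-fed gilts 4 of 19 members had a positive change and 5 fell, over all genes tested and adjusted over the list alone, with a median of -0.46 (list adjusted p = 0.0385; adjusted p = 0.412 with an estimated correlation). INSR went from 869 ± 180.2 to 162 ± 115, the IGF-binding protein gene IGFBP4 fell by 0.94 ± 0.18, IGF2R fell by 0.84 ± 0.17 and IGF1R fell by 1.00 ± 0.24. Of 25 hypoxia response genes 7 had a positive change, 4 fell over all genes tested and 5 adjusted over the list alone, with a median of -0.26 (list adjusted p = 0.0385; adjusted p = 0.412 with an estimated correlation). P4HA1 fell by 1.06 ± 0.21, the stress-induced gene NDRG1 fell by 2.03 ± 0.53, EGLN3 fell by 0.76 ± 0.21 and EPAS1, an oxygen-regulated transcription factor of endothelium, fell by 2.24 ± 0.65. The members that fell over all genes tested without the 3 libraries of high DES numbered 1 for immediate early genes, 2 for endothelium, 3 for glucocorticoid-responsive genes, 2 for the IGF system and 1 for hypoxia response, while these lists still passed. There EPAS1, NDRG1, INSR and IGF1R changed by -1.22, -1.29, -1.71 and -0.60. The calls on EPAS1, EGLN3, P4HA1, IGF1R, IGF2R, KLF9, KLF6, EGR2, C-JUN, FLT4, FLT1 and PECAM1 ended (adjusted p from 0.0582 to 0.206). Given the axis score, EPAS1, NDRG1, INSR, IGF1R, IGF2R, KLF6, EGR2 and FLT1 changed by -0.87, -0.88, -1.39, -0.63, -0.53, -0.83, -1.13 and -1.02. The calls on EPAS1, EGLN3, IGF1R, KLF6, EGR2, FLT1 and PECAM1 ended there (adjusted p from 0.0566 to 0.198).

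In all, 1299 genes rose and 1232 fell of 16862 tested with limma, 6245 had an unadjusted p under 0.05, and 1573 of those past the threshold changed at least 2-fold. The libraries did not overlap for 28.3% of genes, where chance gives 2.86%. In place of 2531 genes, 1645 passed without PND0 1, 1358 without PND0 3, 871 without PND0 4, 549 without PND2R 2, 571 without PND2R 3 and 4101 without PND2N 1. PND2R 2 and PND2R 3 are 2 of the 3 libraries of high DES: without PND2N 1, PND2R 2 and PND2R 3 together 254 genes passed, 232 of them among the 2531, and with their axis as a covariate 1355. The fit without the 3 libraries holds only 2 replacer-fed libraries. A call that ended there need not rest on the libraries left out, and all of the 2531 genes kept their sign. The median change of all genes was -0.06 as deposited and 0.05 after quantile normalization, a shift of 0.11. Of 67 calls on genes named for this comparison, 30 held whichever library was left out, 21 held without the 3 libraries together and 40 with their axis as a covariate. Without PND0 1, 2, 3 or 4 the number of these calls lost was 14, 13, 20 or 33. It was 0, 5, 2 or 8 without PND2N 1, 2, 3 or 4, and 2, 36, 34 or 11 without PND2R 1, 2, 3 or 4. The lists of oxidative phosphorylation, cell cycle, interferon response, cytokines and immediate early genes were called in all 12 fits that left out a library. Without PND2R 1 the adjusted p was 0.0812 for endothelium, glucocorticoid-responsive genes, hypoxia response and the IGF system. Without PND2R 4 it was 0.0593 for endothelium, 0.0629 for glucocorticoid-responsive genes, 0.0629 for hypoxia response and 0.0569 for the IGF system. Leaving out PND0 4 gave 0.0529 for ribosomal proteins and 0.0906 for the IGF system, PND0 3 gave 0.0537 for the IGF system, and PND0 2 gave 0.118 for hypoxia response.

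Many genes changed in the same direction after nursing and after replacer feeding. MMP7, CCL8, SKA1, AURKA, CCNB2, NDUFS4 and CCL2 rose in both comparisons with birth, and ZBTB16, GREB1, IGF1R, IGF2R and EGLN3 fell in both. Across genes, 305 rose in both and 226 fell in both, where lists independent of each other would share 24.8 and 17.4, a product that leaves out the shared newborn libraries. In 100 simulations with no change, limma called 0 genes in both comparisons. A single gene, LOC100514492, moved in opposite directions, with a change of -3.49 ± 0.32 in PND2N and of 1.63 ± 0.32 in PND2R. Of the genes past the threshold, 28 passed in PND2N alone and 1999 in PND2R alone, but a gene that passes in one comparison and not in the other is not thereby shown to differ. The log2 changes correlated across 16862 genes with a Pearson r of 0.900 and a Spearman rho of 0.901, where genes are not independent replicates. Part of this comes from the PND0 libraries that both comparisons share: in 100 simulations with no change, the mean Pearson r was 0.372 (95% of them between -0.709 and 0.942). The covariance of the changes was 0.668 against a simulated mean of 0.0928 and an upper end of 0.480 for the same 95%. With separate newborn libraries for each comparison, 2 and 2, the mean Pearson r over 6 assignments was 0.705, from 0.507 to 0.809. The lowest came where PND0 1 and PND0 2 served one comparison and PND0 3 and PND0 4 the other. The genes that rose in both then numbered 0 to 249 and those that fell in both 0 to 182, with at most 2 of either in the 4 assignments that did not part the newborn libraries in this way.

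**Figure D2:**
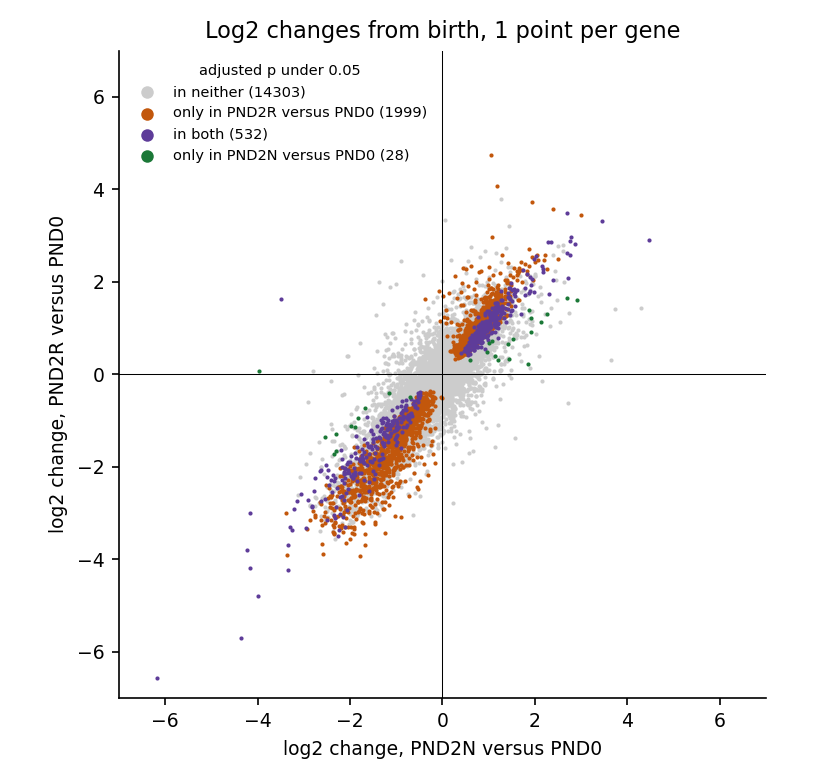
Log2 change from birth in nursed gilts (horizontal axis) against the log2 change from birth in replacer-fed gilts (vertical axis), 1 point for each of 16862 genes, colored by the comparisons in which its adjusted p was under 0.05. Most genes past the threshold lie near the diagonal, with 305 that rose in both, 226 that fell in both and 1 that moved in opposite directions.

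The comparison of PND2N with PND2R asked how nursing and replacer feeding differed at the same age, and it is also the test of whether the changes from birth differed. LOC100514492, an uncharacterized gene (chromosome 13, 65432520 to 65460967), stood at 1.23 ± 0.318 in nursed and 76.9 ± 10.22 in replacer-fed gilts, a log2 difference of -5.13 ± 0.32 (adjusted p = 2.16e-05), and at 24.9 ± 7.13 at birth. It lies within the interval of SUMF1, a sulfatase-modifying enzyme, whose own difference was 0.034 ± 0.26. LOC100518566, annotated as similar to TMEM126B (chromosome 9, 22290442 to 22297782), stood at 5.05 ± 2.00 and 105 ± 55.6, a difference of -4.03 ± 0.45 (adjusted p = 0.00999), and at 94.6 ± 35.01 at birth. TMEM126B itself, a factor of complex I assembly on the same chromosome (22440635 to 22448240), was at 384 ± 28.2 and 207 ± 25.6 and did not pass. LOC100514492 and LOC100518566 were the only genes of 16862 to pass, both lower in nursed gilts in all libraries, and these genes, TMEM126B and SUMF1 were chosen after their values were seen. At an unadjusted p under 0.05 there were 452 genes, and the libraries of the groups did not overlap for 2.55% of genes, where chance gives 2.86%. Both genes passed without the 3 libraries of high DES. The LOC100518566 call ended without PND2N 2 (adjusted p = 0.0507), PND2N 4 (adjusted p = 0.0709), PND2R 1 (adjusted p = 0.0645) or PND2R 4 (adjusted p = 0.0618), and with only the groups compared in the fit (adjusted p = 0.197).

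With the preset correlation, 6 gene lists were called between feeding groups, although none of their members passed over all genes in limma. Of the 35 splits of these 8 libraries into 4 and 4, 16 called as many lists, so chance cannot be excluded for their number. Of 21 cholesterol synthesis genes 5 were higher in nursed gilts, with a median of -0.26 (list adjusted p = 4.81e-05; adjusted p = 0.429 with an estimated correlation). STARD4, a sterol carrier, was at 321 ± 113 in nursed and 548 ± 169.9 in replacer-fed gilts, mevalonate kinase (MVK) at 772 ± 451 and 1320.4 ± 522, ACAT2, which makes acetoacetyl-CoA, at 2395 ± 985 and 3618 ± 1130.5, and the sterol desaturase SC5D at 1784 ± 320.4 and 2224 ± 181. Of 26 fatty acid oxidation genes 17 were higher in nursed gilts, 1 when adjusted over the list alone, with a median of 0.15 (list adjusted p = 0.0136; adjusted p = 0.429 with an estimated correlation). CPT1A was at 8157 ± 1327 and 4832 ± 72.7 (adjusted p = 0.665), the fatty acid receptor CD36 at 293 ± 106 and 97.3 ± 21.4, the dehydrogenase ACADL at 1281 ± 298 and 856 ± 181, and PDK4, an inhibitor of pyruvate oxidation, at 1771 ± 758 and 866 ± 457. Of 17 endothelium markers 14 were higher in nursed gilts, with a median of 0.25 (list adjusted p = 0.00913; adjusted p = 0.463 with an estimated correlation). The differences were 0.86 ± 0.32 for the angiopoietin receptor TEK, 0.53 ± 0.23 for PECAM1, 0.54 ± 0.25 for TIE-1 and 0.73 ± 0.44 for the sialomucin EMCN. Of 24 interstitial matrix genes 18 were higher in nursed gilts, with a median of 0.19 (list adjusted p = 0.0425; adjusted p = 0.593 with an estimated correlation). SPARC, a collagen-binding protein, differed by 0.34 ± 0.11, the collagens COL5A1 and COL14A1 by 0.64 ± 0.27 and 0.35 ± 0.26, and elastin (ELN) by 0.36 ± 0.18. Of 10 ciliated and oviduct epithelium markers 3 were higher in nursed gilts, with a median of -0.37 (list adjusted p = 0.0425; adjusted p = 0.546 with an estimated correlation). FOXJ1, the regulator of motile cilia, was at 539.99 ± 354 and 873 ± 401, the ciliary tektin TEKT1 at 27.7 ± 9.29 and 41.0 ± 13.1, and the dynein genes DNAI1 and DNAH9 differed by -1.12 ± 0.34 and 0.39 ± 0.29. Of 44 ribosomal protein genes 8 were higher in nursed gilts, with a median of -0.14 (list adjusted p = 0.0136; adjusted p = 0.785 with an estimated correlation). RPL38, RPS13, RPL26 and RPL30 differed by -0.29 ± 0.28, -0.21 ± 0.22, -0.22 ± 0.23 and 0.39 ± 0.44. At an unadjusted p under 0.05 there were 3 members of the cholesterol list, 4 of fatty acid oxidation, 3 of endothelium, 2 of interstitial matrix, 1 of the ciliated list and 0 of the ribosomal proteins.

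The cholesterol list was called with the preset correlation in all 12 fits that left out a library, with a highest adjusted p of 0.0243. Without PND2N 1 the adjusted p was 0.0729 for fatty acid oxidation, 0.111 for endothelium and 0.0784 for interstitial matrix. Without PND2R 1 it was 0.0593 for fatty acid oxidation, 0.145 for endothelium, 0.157 for interstitial matrix and 0.149 for the ciliated list. Without PND2R 4 it was 0.0544 for fatty acid oxidation, 0.0965 for interstitial matrix and 0.0992 for the ciliated list. Leaving out PND2N 2 gave 0.262 for interstitial matrix, 0.379 for ribosomal proteins and 0.373 for the ciliated list, and leaving out PND2N 4 gave 0.0596 for the ciliated list. The ciliated call also ended with the axis score as a covariate (adjusted p = 0.0869), and its median was -0.66 without the 3 libraries of high DES. For ribosomal proteins, leaving out PND2R 2 gave 0.206, PND2R 3 gave 0.362, and PND2N 3 gave 0.350 with a median of 0.038. The ribosomal call was also absent without the 3 libraries of high DES (adjusted p = 0.162) and with the axis score (median -0.029, adjusted p = 0.640). The endothelium median was 0.40 without the 3 libraries.

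**Figure D3:**
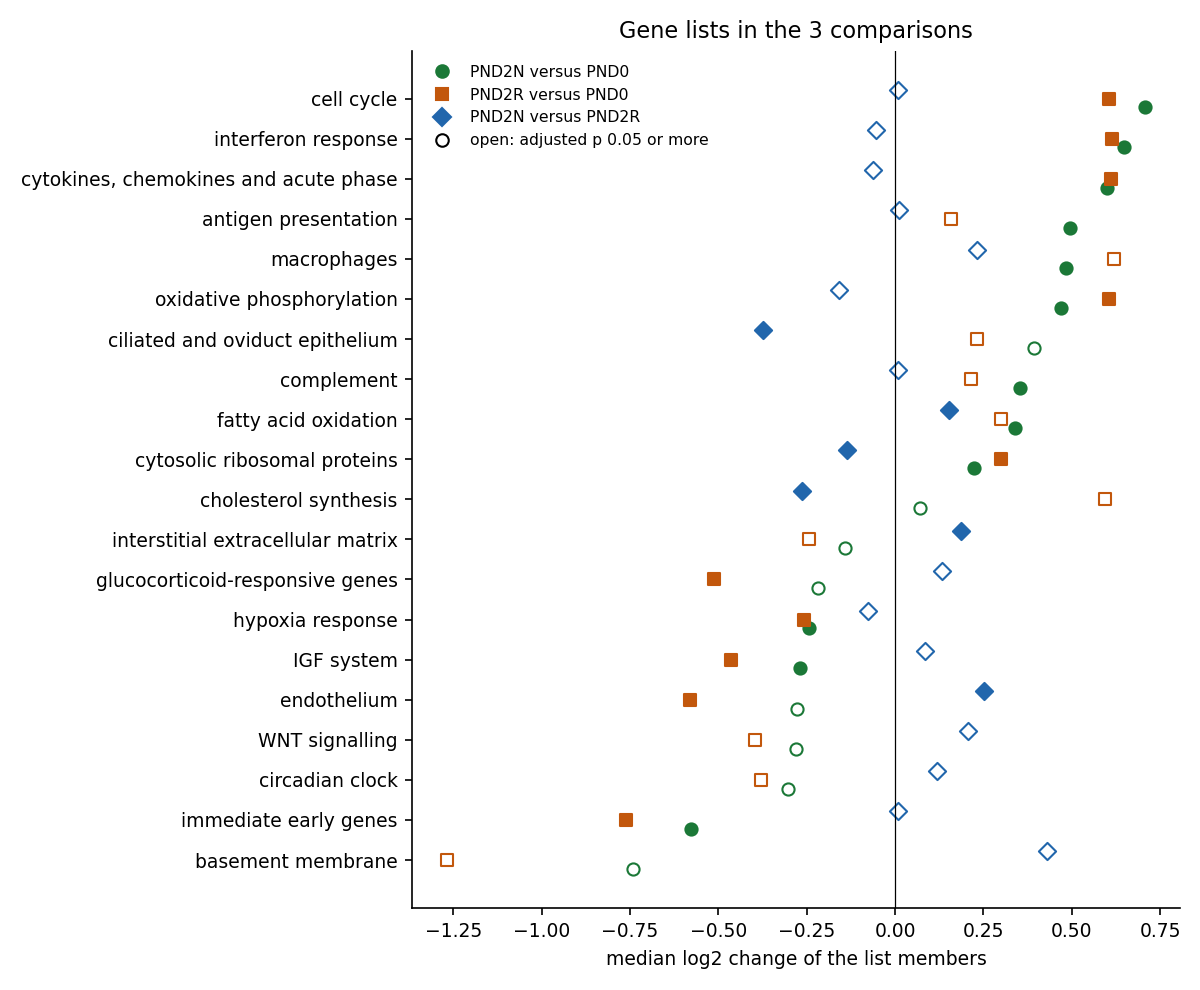
Median log2 change of the members of 20 gene lists (horizontal axis) in the 3 comparisons, with filled symbols where the list's adjusted p was under 0.05 with the preset correlation. Cell cycle, interferon, cytokine and oxidative phosphorylation genes lie to the right of 0 in both comparisons with birth, and cholesterol synthesis lies at -0.26 between feeding groups.

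Steroid receptor and uterine patterning genes were read in every comparison. ESR1, the estrogen receptor, rose from 2207 ± 1066 at birth to 5638 ± 1517 in nursed gilts (1.46 ± 0.33; adjusted p = 0.0404) and 4887 ± 977 in replacer-fed gilts (1.27 ± 0.33; adjusted p = 0.0286). WNT4, a WNT ligand of Müllerian development, rose in replacer-fed gilts from 159 ± 49.6 to 382 ± 109 (adjusted p = 0.0323) and was 244 ± 93.3 in nursed gilts without passing (adjusted p = 0.307). VEGFA, which fell in nursed gilts, was 3543 ± 281 in replacer-fed gilts against 5058 ± 947 at birth (adjusted p = 0.0558). The progesterone receptor PGR was 310.4 ± 67.6 at birth, 104 ± 75.5 and 78.9 ± 47.3 at day 2, and passed in neither comparison (adjusted p = 0.106 and adjusted p = 0.0542). FOXA2, a regulator of uterine gland development, was 43.4 ± 39.1, 27.5 ± 9.64 and 160.5 ± 106, with a difference between feeding groups of -2.28 ± 0.94 that did not pass. The newborn values of ESR1 ran against the keratin split, with 1035, 1574, 3184 and 3033 in PND0 1 to PND0 4. Those of FOXA2 followed it, with 89.4, 60.0, 1.52 and 22.6 in PND0 1 to PND0 4, as did those of WNT7A, a WNT ligand of uterine epithelium, with 7545, 5954, 870 and 1444. WNT7A means were 3953 ± 3302, 6306 ± 1819 and 6049 ± 461 in PND0, PND2N and PND2R, and those of WNT5A, a WNT ligand of stroma, 4722 ± 745, 2593 ± 1749 and 1929.6 ± 1353. The relaxin receptor RXFP1 had changes from birth of 0.65 ± 0.27 and 0.70 ± 0.27 in PND2N and PND2R, and the gelatinases MMP9 and MMP2 changes of 1.44 ± 0.47 and 0.79 ± 0.47, and 0.20 ± 0.18 and 0.13 ± 0.18. For the growth factor IGF1 the changes were -0.40 ± 0.46 and -0.39 ± 0.46, for the growth hormone receptor GHR -0.12 ± 0.27 and -0.19 ± 0.27, and for the prolactin receptor PRLR 0.016 ± 0.32 and -0.22 ± 0.32. For the oxytocin receptor OXTR they were -0.0064 ± 0.46 and -0.69 ± 0.46, and for the patterning genes HOXA10 and HOXA11 -0.20 ± 0.27 and -0.24 ± 0.27, and -0.058 ± 0.28 and -0.16 ± 0.28. None of the 17 panel genes measured passed between the feeding groups, and IGF2 and MKI67 were not matched in the table. Among the fits that left out a library, the ESR1 call in nursed gilts held only without PND0 3 or PND2R 1 (adjusted p from 0.0531 to 0.0948 in the other 10). It also ended with plain empirical Bayes (adjusted p = 0.0526), with only the groups compared (adjusted p = 0.0980) and without the 3 libraries of high DES (adjusted p = 0.0672). In replacer-fed gilts it ended without PND0 1, PND0 2, PND2R 2, PND2R 3 or PND2R 4 (adjusted p from 0.0538 to 0.0714) and without the 3 libraries (adjusted p = 0.0969). The WNT4 call ended without PND0 1, PND0 2, PND0 4, PND2R 2, PND2R 3 or PND2R 4 (adjusted p from 0.0509 to 0.105), without the 3 libraries (adjusted p = 0.192) and with the axis score (adjusted p = 0.124). The VEGFA call held only without PND0 2 (adjusted p from 0.0523 to 0.125 in the other 11 such fits) and ended with plain empirical Bayes (adjusted p = 0.0620) and with only the groups compared (adjusted p = 0.110). Without PND0 1 the newborn mean of FOXA2 was 28.0. The OXTR, PRLR, GHR, FOXA2 and HOXA11 changes after nursing and the MMP2, OXTR, GHR, PRLR and HOXA11 changes after replacer feeding took the other sign under some settings or without a library.

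**Figure D4:**
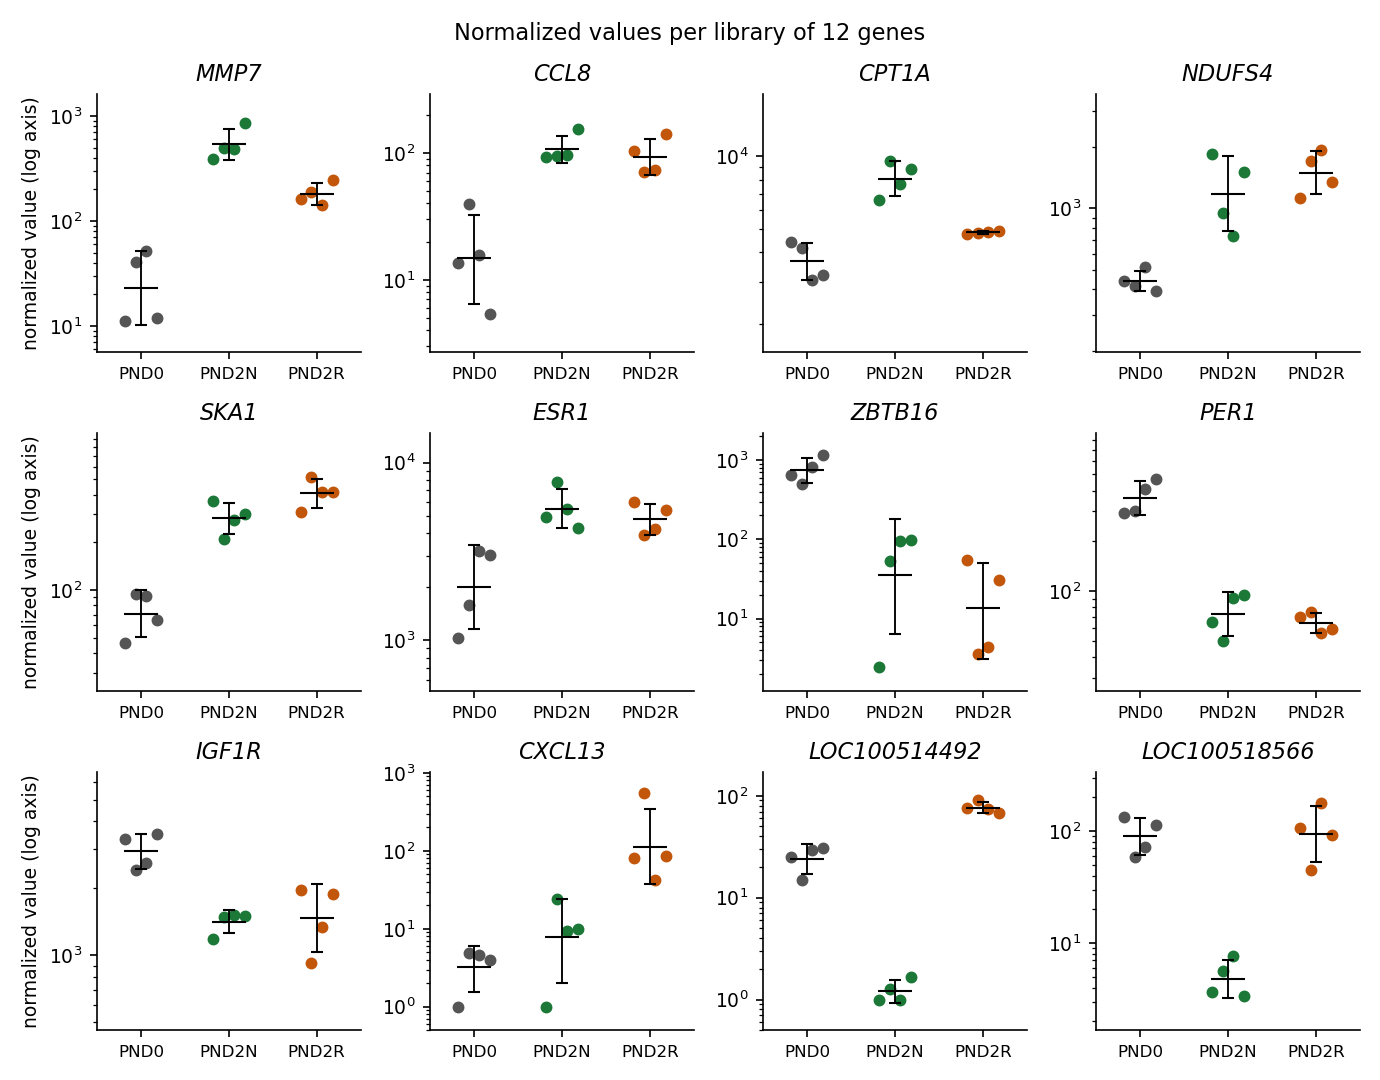
Normalized value (log axis) of 12 genes in each of the 12 libraries, by group, with points for single libraries and a bar and whiskers at the mean and 1 SD of log2(value + 1). MMP7, CCL8, NDUFS4 and SKA1 lie above their newborn values in both feeding groups, and LOC100514492 lies near 1 in the nursed libraries alone.

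Taking the groups jointly, the limma F test found 1084 genes that differed among the 3 groups, and 4711 had an unadjusted p under 0.05. Of these 1084 genes 715 differed at least 2-fold from birth in PND2N or PND2R. Without PND0 1, 2, 3 or 4 the count was 349, 626, 362 or 114. It was 1690 without PND2N 1, 712 without PND2N 2 and 420 without PND2N 4. It was 357, 380 and 444 without PND2R 2, PND2R 3 and PND2R 4, and 283 without the 3 libraries of high DES.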

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

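Tests chosen after the results were seen were the scaling test and the summed value of LOC100518566 and TMEM126B; the other tests were fixed before the values they measure were seen.

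The libraries PND2N 1, PND2R 2 and PND2R 3 lay apart from the other 9 on the first within-group axis, which held 55.2% of the variance within groups. Taking out a smooth trend with gene span left 91.558% of the axis variance, so such a trend accounts for little of it. The gene loadings on the axis correlated with log span (Spearman rho 0.293 in size). Span only stood in for transcript length, so the test cannot decide on a cause tied to length or RNA quality. Scaling between libraries is argued against, since 90.823% of the axis's share was kept under quantile normalization. A different share of another cell type stays open: 2 cell type lists, smooth muscle (median loading -0.33) and skeletal muscle (-0.48), had median loadings toward these libraries beyond those of matched random lists (the first at the smallest p that 10000 lists can give, 2.0e-04), with DES at 40049, 33144 and 29022. The random lists were drawn gene by gene, whereas genes of a marker list move together (estimated correlation 0.279 for smooth muscle and 0.283 for skeletal muscle). The p of this test can therefore be too small. Of 13 skeletal muscle genes matched only 7 were high enough to be tested, uterus holds smooth muscle of its own, and no biological explanation was tested.

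PND0 1 and PND0 2 lay apart from PND0 3 and PND0 4 on the second within-group axis, with 18.4% of the variance within groups. Taking out the span trend left 97.944% of the axis variance (Spearman rho of the loadings with log span 0.161 in size). This again leaves length and RNA quality open. A different share of another cell type stays open: 4 cell type lists lay beyond random lists, epithelium (-0.71, with 95.0% of 20 members on one side), squamous epithelium (-0.39) and neutrophils (-0.28), all higher in PND0 1 and PND0 2, and smooth muscle (0.17), higher in PND0 3 and PND0 4. KRT8 stood at 49821, 51645, 14444 and 11100 in the 4 libraries. Here too the genes of a marker list move together (estimated correlation 0.582 for epithelium), which random lists drawn gene by gene do not. Uterus holds epithelium of its own, so the lists cannot place the cells, and no biological explanation was tested.

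LOC100514492 and LOC100518566 were near the lowest value in all 4 nursed libraries, with differences between the feeding groups of -5.13 and -4.03 on the log2 scale (-5.1259 and -4.0285), which are also the tested differences of their changes from birth. For LOC100518566, reads shared with TMEM126B cannot be told apart from a loss of the gene beside a separate rise of TMEM126B (384 ± 28.2 against 207 ± 25.6), since either gives the same sum. The summed value of both genes differed by 0.32455 on the log2 scale, 389 ± 27.2 in PND2N against 313 ± 48.4 in PND2R (exact permutation p = 0.0571, two-sided, smallest possible p = 0.0286), which argues only against a loss with TMEM126B unchanged, for which the difference would be -0.56. For both genes a litter or donor variant cannot be told apart from feeding, since no litter is named, and 4 other genes that were either at most 2 or at least 20 in every library had these levels across groups, in all 4 cases. Nursing against replacer feeding itself stays open as an untested explanation.

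The libraries were also split in other ways. For genes in PND2N versus PND0, 1 of the 35 splits, the real one, gave as many as 560, and the highest other gave 351. This is the smallest share that 35 splits can give, so chance is made unlikely but not excluded. For genes in PND2R versus PND0, 1 of the 35 splits gave as many as 2531, and the highest other gave 1, so chance is again made unlikely but not excluded. For genes in PND2N versus PND2R, 3 of the 35 splits gave as many as 2, so chance cannot be excluded. The highest other gave 6202, with PND2N 1, PND2N 4, PND2R 2 and PND2R 3 on one side, which points to a structure of the samples along the axis of high DES. For the F test 3 of 100 splits, the real one included, gave as many as 1084, few enough for the bound set beforehand. The highest other gave 5523, with PND2N 1, PND2N 4, PND2R 2 and PND2R 3 again in one group, which also points to that structure. Another mixed split gave 4419, with PND2N 1, PND2R 2, PND2R 3 and PND2R 4 in one group, so it too gathers the 3 libraries of high DES. The real count met the bound, but splits along this structure exceed it, so the count does not exclude chance. For the number of lists called, 6 of the 35 splits gave as many as 12 in PND2N versus PND0 (highest other 18), 9 gave as many as 10 in PND2R versus PND0 (highest other 18) and 16 gave as many as 6 in PND2N versus PND2R (highest other 13), so chance cannot be excluded for the number of lists.

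Between the changes of the nursed and of the replacer-fed gilts from birth, 6 lists were called with the preset correlation by the test of the difference itself. The median differences were -0.263 for cholesterol synthesis, 0.253 for endothelium, 0.185 for interstitial extracellular matrix, 0.152 for fatty acid oxidation, -0.135 for cytosolic ribosomal proteins and -0.375 for ciliated and oviduct epithelium. None of the 6 calls held with an estimated correlation (adjusted p from 0.429 to 0.785).

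Of 426 groups of 4 values of the named genes, 25 had a highest or lowest library far from the other 3, with a gap larger, as a share of the range, than the bound of the Dixon test for 4 values. Chance flags about 1 in 20 groups, here 21.3. In PND2N 1 they were IRS1 (0.846), IGF1R (0.919), ANKRD37 (0.848) and EGR2 (0.863), in PND2N 2 BBOX1 (0.873) and ACAA2 (0.851). In PND2N 3 they were PPP1R3G (1.0), HSD17B7 (0.912) and RXFP1 (0.884), in PND2N 4 CCL8 (0.926), HERC5 (0.909) and IGF1 (0.902). In PND2R 1 they were GREB1 (1.0) and FLT4 (0.8303), in PND2R 2 C-JUN (0.901), FOS (0.882), EGLN3 (0.838), CD59 (0.908) and WNT7A (0.912), in PND2R 3 RPL30 (0.853), in PND2R 4 LHX4 (1.0). In the newborn group they were CXCL13 (0.834) and AURKB (0.917) in PND0 1, SLC39A12 (0.926) in PND0 3 and WNT5A (0.835) in PND0 4.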

How the results depend on the processing

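Tests without the 3 libraries that stand apart and with the axis score as a covariate, and the share of the first component under other settings, were chosen after seeing the data; the other settings were fixed earlier. The count test was not run, because the values are not counts. Over all settings, 4157 of the values for named genes kept their direction and side of the threshold, 605 no longer passed, 64 now passed and 66 changed sign; for lists these numbers were 450, 81, 10 and 3. Of the counts and measures of structure 127 stayed within 1.5 times (for the correlation and the component, within 1 SD of the values with a library left out) and 61 did not. Every gene past the threshold in a comparison kept its sign under TMM, quantile normalization, library quality weights, the axis score as a covariate and the 3 libraries left out, while the number of calls shared with the full fit was 543, 451, 515, 529 and 214 of 560 for PND2N versus PND0 and 2473, 2163, 2094, 967 and 232 of 2531 for PND2R versus PND0. Where fewer libraries entered a fit, fewer also estimated the spread. The axis score differs between newborn and day 2 libraries, so as a covariate it can take out part of a change from birth. Otherwise the cause was not tested.

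For PND2N versus PND0 the 560 genes became 275 without the 3 libraries, 1213 with the axis score, 7 with only the groups compared in the fit, 327 with at least a 2-fold change, and 26 (without PND2N 4) to 645 (without PND2N 3) with a library left out. For PND2R versus PND0 the 2531 genes became 254, 1355 and, at 2-fold, 1573, and 549 (without PND2R 2) to 4101 (without PND2N 1). For PND2N versus PND2R the 2 genes became 6 with library quality weights, 5 without the 3 libraries, 1 with only the groups compared, and 1 to 3 with a library left out (3 without PND2R 2). For the F test the 1084 genes became 283 without the 3 libraries, 715 at 2-fold, and 114 (without PND0 4) to 1690 (without PND2N 1). The correlation of the changes from birth, 0.900, became 0.809 with quality weights, 0.749 without the 3 libraries, 0.818 with the axis score, 0.705 with PND0 split, and 0.766 (without PND2N 1) to 0.917 (without PND2N 3). The share of the first component, 58.5%, became 61.7% with 5 added, 62.7% with the stricter filter, 53.9% after quantile normalization, 38.6% without the 3 libraries, and 53.8% (without PND2N 1) to 60.7% (without PND0 3). The number of lists called fell from 12, 10 and 6 to 1, 0 and 0 with an estimated correlation and was 12 without the 3 libraries in PND2N versus PND2R; with a library left out it ran from 7 (without PND0 4) to 14 (without PND0 2) in PND2N versus PND0, 6 (without PND2R 1 or PND2R 4) to 14 (without PND0 1) in PND2R versus PND0 and 3 (without PND2R 1) to 10 (without PND2R 3) in PND2N versus PND2R.

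Values that changed sign were mostly small. The ribosomal median became -0.052 in PND2N versus PND0 and -0.011 in PND2R versus PND0 with the axis score. In PND2N versus PND2R it ran from -0.27 (without PND2N 1) to 0.038 (without PND2N 3).

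In PND2N versus PND0, OXTR became 0.0058 with 5 added, 0.0094 under TMM, 0.45 after quantile normalization, 0.11 with quality weights, 0.30 without the 3 libraries and 0.57 with the axis score. It ran from -0.20 (without PND2N 3) to 0.30 (without PND2N 1). PRLR became -0.023 after quantile normalization, -0.036 without the 3 libraries and -0.13 with the axis score, and ran from -0.21 (without PND0 2) to 0.25 (without PND0 4). GHR became 0.17 with weights, 0.056 without the 3 libraries and 0.11 with the axis score, and ran from -0.30 (without PND0 1) to 0.056 (without PND2N 1). FOXA2 became -0.043 with 5 added and -0.20 with weights, and ran from -0.89 (without PND0 3) to 0.83 (without PND0 1). HOXA11 ran from -0.23 (without PND0 1) to 0.14 (without PND2N 3). In PND2R versus PND0, MMP2 became -0.018 without the 3 libraries and -0.028 with the axis score, which also gave 0.13 for OXTR and 0.14 for GHR. PRLR ran there from -0.45 (without PND0 2) to 0.012 (without PND0 4) and HOXA11 from -0.33 (without PND0 1) to 0.014 (without PND0 3).

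In PND2N versus PND2R, ESR1 became -0.0014 without the 3 libraries. IGF1 became 0.11 with weights, 0.24 without the 3 libraries and 0.046 with the axis score, and ran from -0.13 (without PND2R 1) to 0.16 (without PND2R 3). RXFP1 became 0.026 with weights and ran from -0.14 (without PND2N 4) to 0.18 (without PND2N 3). PGR became -0.044 after quantile normalization and -0.33 with the axis score, and ran from -0.38 (without PND2N 3) to 0.84 (without PND2N 1). WNT5A became -0.11 with the axis score and ran from -0.037 (without PND2N 3) to 1.01 (without PND2N 1). WNT7A became -0.088 with weights and ran from -0.15 (without PND2N 4) to 0.18 (without PND2N 2). GHR became -0.030 with the axis score and ran from -0.086 (without PND2N 2) to 0.25 (without PND2N 1). MMP2 ran from -0.036 (without PND2N 2) to 0.22 (without PND2N 3), HOXA11 from -0.072 (without PND2N 1) to 0.295 (without PND2N 3) and HOXA10 from -0.057 (without PND2R 1) to 0.18 (without PND2R 2).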

Other observations

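The gene groups of this part were chosen after the results were seen, and no hypothesis of its own was tested. PER1 was lower than at birth in both day 2 groups, with 50.3 to 95.3 in nursed gilts against 294 to 470 at birth. The clock list passed in neither comparison with birth (list adjusted p = 0.119 after nursing). Between birth and day 2 with milk replacer, clock genes moved individually although their list did not pass. PER1, a repressor of the clock, fell from 368 ± 85.3 to 65.0 ± 8.95 (adjusted p = 0.00391, n = 4 per group), CRY1 from 1882 ± 494 to 992 ± 329.5 and CRY2, partners of the PER proteins, from 1731 ± 241 to 936 ± 122, while the clock output gene DBP rose from 717 ± 92.8 to 1795 ± 830.1. Of 14 circadian clock genes 1 rose and 3 fell over all genes tested, and 1 rose and 4 fell adjusted over the list alone (list adjusted p = 0.111; adjusted p = 0.412 with an estimated correlation). The changes of DBP and CRY1 were 0.59 (adjusted p = 0.187) and -0.52 (adjusted p = 0.323) without the 3 libraries of high DES, and with the axis score 0.47 (adjusted p = 0.0905) and -0.55 (adjusted p = 0.197). Some basement membrane genes fell as well: the type IV collagen chains COL4A1 and COL4A2 went from 16646 ± 3467 to 6881 ± 2283 and from 4934 ± 973 to 1550.5 ± 803, and the laminin chain LAMC1 and the nidogen NID2 fell by 0.60 ± 0.17 and fell by 1.20 ± 0.37. Of 14 members 4 fell over all genes tested, and 1 rose and 6 fell adjusted over the list alone, with a median of -1.27 (list adjusted p = 0.0558; adjusted p = 0.578 with an estimated correlation). Without the 3 libraries of high DES that median was -0.40, and the list passed after quantile normalization (adjusted p = 0.0136) and without PND0 1 (adjusted p = 0.0437), PND2N 1 (adjusted p = 0.0433) or PND2N 2 (adjusted p = 0.0376). The calls on COL4A1, COL4A2, LAMC1 and NID2 ended without these 3 libraries (adjusted p from 0.0966 to 0.233), with changes of -0.99, -1.12, -0.41 and -0.86. With the axis score the changes were -0.84, -0.93, -0.36 and -0.50, and of these only the COL4A2 call held (adjusted p = 0.0298).

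Among 28 WNT signaling genes 4 rose and 4 fell over all genes tested, and 4 rose and 5 fell adjusted over the list alone, in replacer-fed gilts against birth (list adjusted p = 0.230; adjusted p = 0.501 with an estimated correlation). The WNT receptor FZD4 fell from 1066 ± 634 to 177 ± 60.2, the ligand WNT16 from 164 ± 15.1 to 72.1 ± 25.2 and the WNT antagonist DKK2 from 1404 ± 432 to 741 ± 162, while LEF1, a transcription factor that acts with beta-catenin, rose from 2657 ± 492 to 4683 ± 539.9. Among 21 cholesterol synthesis genes 4 rose over all genes tested, and 9 rose and 4 fell adjusted over the list alone, with a median of 0.59 (list adjusted p = 0.0558; adjusted p = 0.501 with an estimated correlation). Without the 3 libraries of high DES the median was 0.37 and 0 members rose over all genes in limma, yet the list passed (adjusted p = 0.0128), as it did with the axis score (adjusted p = 0.0210) and without PND0 1 (adjusted p = 0.0485), PND0 3 (adjusted p = 0.0497), PND2N 1 (adjusted p = 0.0433) or PND2R 2 (adjusted p = 0.0262). The sterol isomerase EBP rose by 1.01 ± 0.25, ACAT2 by 0.96 ± 0.27, the sterol carrier STARD4 by 1.08 ± 0.31 and the sterol reductase HSD17B7 by 0.72 ± 0.22. Of the 16 genes named in these paragraphs, PER1 and CRY2 passed whichever library was left out. None of the other 14 passed without PND0 4, where 871 genes passed in place of 2531, nor without PND2R 2, where 549 passed. Without the 3 libraries of high DES, PER1, CRY2 and WNT16 passed and the calls on FZD4, DKK2, LEF1, EBP, ACAT2, STARD4 and HSD17B7 ended (adjusted p from 0.0734 to 0.210), with a change of 0.69 for STARD4. The calls on FZD4, LEF1, EBP, ACAT2, STARD4 and HSD17B7 also ended with the axis score (adjusted p from 0.0575 to 0.186), and FZD4, LEF1, EBP, ACAT2 and STARD4 changed by -1.58, 0.54, 0.53, 0.55 and 0.56.

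In the 9 libraries left without PND2N 1, PND2R 2 and PND2R 3, further lists were called between nursed and replacer-fed gilts with the preset correlation. Antigen presentation (median 0.22, adjusted p = 0.00396), macrophages (0.42, adjusted p = 0.00396), erythroid cells (0.56, adjusted p = 0.00244) and matrix proteases and inhibitors (0.19, adjusted p = 0.00404) were higher in nursed gilts. So were nerve and Schwann cells (0.62, adjusted p = 0.0193), imprinted growth genes (0.22, adjusted p = 0.0401) and glucocorticoid-responsive genes (0.082, adjusted p = 0.0409). With all 12 libraries none of these passed, with an adjusted p from 0.0960 to 0.510. Only 2 replacer-fed libraries are left among the 9, and with an estimated correlation the adjusted p of these lists there ran from 0.321 to 0.523.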
